A study of Homo sapiens with 2 samples.

How the data were processed

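The series holds 2 arrays of the human cell line K562, 1 labelled as treated with PMA at 20 nM for 48 h and 1 labelled as treated with the solvent DMSO. Cells were grown in RPMI1640 medium with fetal bovine serum, total RNA was isolated with a mirVana kit, and cRNA was labelled with Cy3 by the Quick-Amp kit, per the labels' protocols. Each file is the scanner output of 1 single-colour array of a human Agilent design. Signals were extracted with Agilent Feature Extraction 10.7.3.1 under the protocol GE1_107_Sep09, per the file headers, while the submitters' processing notes name Feature Extraction 9.5.3. The deposited processed signal of each spot is an intensity on a linear scale that was background-subtracted with spatial detrending and multiplicatively detrended within the array, per the file headers. The mean spot intensity and the median local background intensity are also deposited and had not been background-subtracted, per the file headers. No scaling between arrays is recorded in the headers.

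Each array held 52857 spots, of which 51538 were not controls and 308 were negative controls. Spots flagged as outliers by the extraction software numbered 69 on each array, and the 133 spots flagged on either array were left out, which left 50200 probes. The spots of a probe were averaged, which concerned 130 probes printed 11 times. The main setting was log2 of the processed signal minus each array's 75th percentile over probes that were neither controls nor outliers. The 75th percentile was 1.12 times as high on the PMA array. A probe counted as measured if the software called it well above background on both arrays, which held for 30752 probes, while 2025 were so on the PMA array only and 3019 on the DMSO array only. The lowest signal called well above background was 13 on the DMSO array and 17.6 on the PMA array, and the highest signals were 301053 and 267873.

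Probes were named through their accession, gene identifier or symbol in a RefSeq gene table of assembly GRCh38.p14 with 59792 genes, which was used for names only. Of the probes, 65.5% received an approved symbol, 28573 by accession, 452 by gene identifier, 2774 by symbol and 1061 by an older symbol, and 17340 stayed without one. The accessions of 458 probes belonged to more than 1 gene. The headers name genome build hg18, for which no sequence or annotation was used here, so no coordinates are given. A gene's value was the mean over its measured probes, and 5517 genes had several. Among these, 14 had probes at least 2-fold in opposite directions, 1263 had probes of opposite sign and 805 had probes over 2-fold apart. A gene with no measured probe but a probe well above background on 1 array received only a bound, the bright array's value minus the higher of the dim array's lowest well-above-background signal and the probe's own value.

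With 1 array per group there are no residual degrees of freedom, so no test was run and no p-value was computed. Genes were counted at a difference of at least 2-fold, and 29 gene lists were described by counts, medians and the percentile of each median among 10000 random lists matched in 20 bins of mean expression. The samples' groups, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names the 12 genes with the largest higher and the 12 with the largest lower difference whose probes were all at least 2-fold apart in one direction, the 5 largest bounds in each direction, up to 4 members of each list with the largest differences, and genes always named, among them GATA1, GATA2, MYC, MYB, KLF1, FLI1, RUNX1, ITGA2B, ITGB3, HBG1 or HBG2, CDKN1A, EGR1 and TFRC. Some genes that the rule selects are not reported here.

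The alternatives were normexp background correction with an offset of 50 on the mean and local background intensities, scaling to each array's median, quantile normalization, no scaling, the 75th percentile over probes well above background on both arrays, no filter on background, a filter at 4-fold above the lowest well-above-background signal, leaving out saturated probes, and the brightest probe of each gene. Counts were also taken at 1.5-fold and 3-fold and over probes in place of genes, and list medians with bounded members at their bound. Scaling to the median of the 7 spike-in probes well above background on both arrays was chosen after seeing the data. Symbol families and 3 added marker lists, of 16 abundant myeloid genes (median 0.42), 18 abundant lymphoid genes (median 0.24) and 14 cytotoxic lymphocyte genes (median 0.06), were also examined after seeing the data. The amounts of spike-in RNA are not stated in the sources used here.

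The steps were tested on simulated data for the PMA against DMSO comparison, drawn from the DMSO array with a spot noise SD of 0.081 and 200 of 14470 genes set to known folds. All genes set 4-fold or 8-fold apart and measured on both simulated arrays came out at least 2-fold apart in the set direction. At exactly 2-fold, 52.9% of the higher and 50.0% of the lower genes did so, since noise falls on both sides of the threshold. Of 33 genes set 8-fold lower, 23 were still measured on both arrays. Of the unchanged genes, 15097 were measured on both simulated arrays, more than the 14470 of the real pair because detection was simulated from the DMSO array alone, and none was at least 2-fold apart, and 6 of 100 lists of unchanged genes fell outside the central range of random lists. This noise is the spread of the log2 difference among spots of one probe and stands for no biological replicate. It was the same at every signal, while the 95th percentile of that SD among real repeated probes was 0.3. Unchanged genes and those set 4-fold or more apart could hardly cross the threshold. The simulation therefore checks the steps, and not the noise of dim genes or the choice of scaling.

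The work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and with limma 3.58.1 in R 4.3.3 for the normexp correction. Control probes other than the spike-ins and negative controls were left out. Both arrays lay on 1 slide, per the file headers, so slide was not used as a block.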

Results

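K562, an established human cell line of chronic myeloid leukaemia, was compared after 48 h in 20 nM PMA, a phorbol ester that activates protein kinase C, and after treatment with the solvent DMSO alone. Total RNA was labelled with Cy3 and hybridised to 1-colour Agilent oligonucleotide arrays, with 1 array per group. Of 50238 probes, 67.3% were well above background on the DMSO array and 65.3% on the PMA array. The 75th percentile of the signal was 414.3 on the DMSO array and 465.1 on the PMA array, against 95th percentiles of 3.22 and 4.41 for the negative-control spots, and no spot was saturated. No difference has a replicate check, because each group had 1 array, and the number of arrays limits the precision of every value. The log2 difference between the arrays had a median SD of 0.081 among spots of a repeated probe, over 89 probes. Among probes of one gene its SD was 0.21 at the median and 0.51 pooled, over 5517 genes. Values are log2 differences, PMA minus DMSO, after each array was scaled to its 75th percentile, for genes well above background on both arrays unless a bound is stated.

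The comparison asked how the transcripts of K562 cells differ after PMA, a treatment the series title ties to differentiation of the line. Several chemokine genes, and immediate early, adhesion and matrix genes as groups, were higher on the PMA array, while erythroid, cell division and ribosome production genes had negative medians as groups. CCL2, a chemokine that attracts monocytes, was 4500-fold higher (12.14), and CD44, the cell surface receptor for hyaluronan, was 1775-fold higher (10.79). Each rests on 1 probe, and CCL2 was dim on the DMSO array (-4.20 relative to the 75th percentile), so such folds are imprecise. HBZ, the embryonic zeta-globin gene, was 43.7-fold lower (-5.45), and KLF1, a transcription factor that drives erythroid genes, was 36.7-fold lower (-5.20). Of 14470 named genes measured on both arrays, 1983 (13.7%) were at least 2-fold higher and 2306 (15.9%) at least 2-fold lower on the PMA array. These counts were 1704 and 2935 under median scaling, 2343 and 1753 without scaling, and 4632 and 592 when scaled to the spike-in probes. Large differences lay mostly on the higher side, with 439 genes at least 8-fold higher and 56 at least 8-fold lower. At 32-fold the counts were 118 higher and 5 lower, the lower ones including HBZ, KLF1 and CNKSR3.

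**Figure D1:**
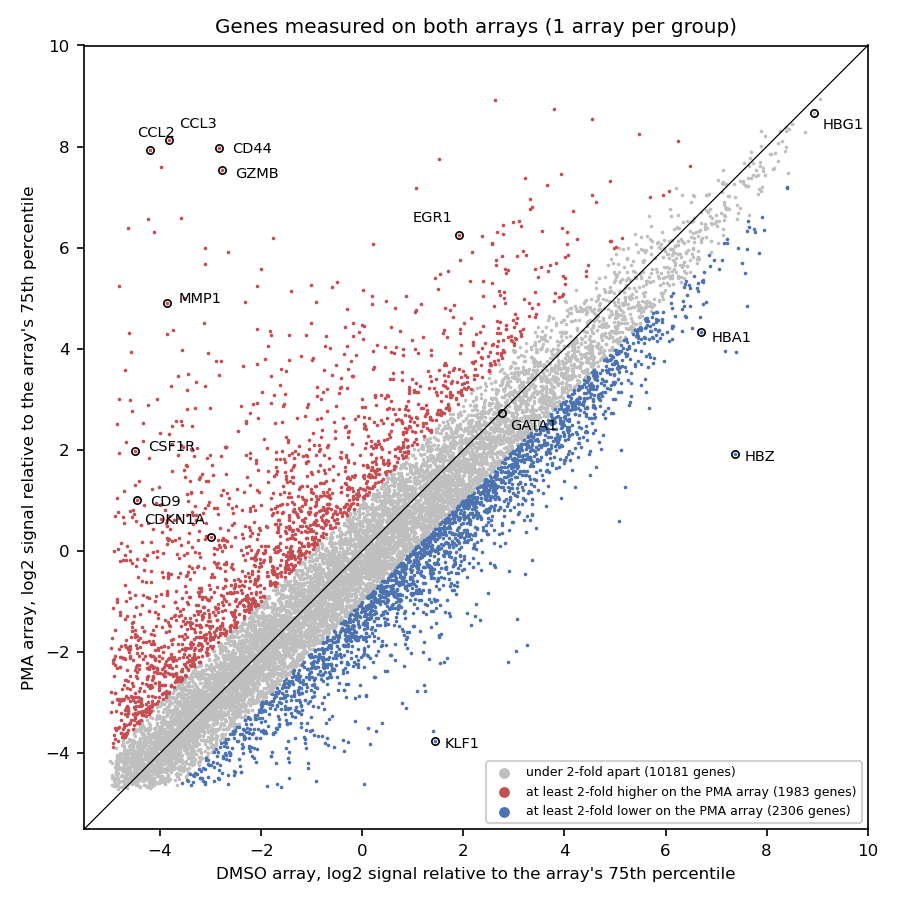
Each point is 1 of the genes measured on both arrays, with its log2 signal relative to the 75th percentile on the DMSO array (x axis) and on the PMA array (y axis). The line marks equal values. Coloured points are the 1983 genes at least 2-fold higher and the 2306 at least 2-fold lower on the PMA array, and CCL2 (12.14) and KLF1 (-5.20) lie far from the line on opposite sides.

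After CCL2, the largest higher differences were those of CCL3 (11.95), CCL4L1 (11.58), CCL4 (11.03), TM4SF1 (10.81), CD44, CCL3L3 (10.43), GZMB (10.31), INHBA (10.17), LOXL2 (10.05), G0S2 (9.10) and BACE2 (8.93). Apart from CCL3L3, each of these values rests on 1 measured probe. Several of the genes were dim on the DMSO array, such as LOXL2 (-4.81), CCL4 (-4.64) and BACE2 (-4.61), which makes their folds imprecise. CCL3 with CCL3L3, and CCL4 with CCL4L1, are near-identical copies whose probes can bind each other's transcripts, so the value of each single copy is uncertain. GZMB encodes a protease of cytotoxic lymphocyte granules, INHBA a subunit of activin, and LOXL2 an enzyme that cross-links collagen. After HBZ and KLF1, large lower differences were those of CNKSR3 (-5.03), PGGT1B (-4.96), SLIT2 (-4.64), HBBP1 (-4.49), MGST1 (-4.42), MNX1 (-4.01), TRIM58 (-3.97) and PKLR (-3.96). Each of these values, like those of HBZ and KLF1, rests on 1 measured probe. Some of these genes were dim on the PMA array, such as SLIT2 (-4.61), TRIM58 (-3.82) and KLF1 (-3.77), so their folds are imprecise too. SLIT2 encodes a secreted guidance protein, HBBP1 is a beta-globin pseudogene, and PKLR encodes the pyruvate kinase of liver and red cells.

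Another 770 genes were well above background only on the PMA array and 826 only on the DMSO array. For these a bound is given, the bright array's value minus the higher of the dim array's lowest well-above-background signal and the probe's own signal there. By this bound 511 genes were at least 2-fold higher and 157 at least 2-fold lower on the PMA array. IL1B, a proinflammatory cytokine, was at least 2756-fold higher (bound 11.43), followed by PAEP (11.37), ATP9A (11.23), TFPI2 (10.50) and IL13RA2 (10.10). HBB, the adult beta-globin gene, was at least 27.6-fold lower (bound -4.78), followed by ABCC9 (-4.50), GARIN5B (-4.46), LPL (-4.41) and LRRD1 (-3.94). The bounds of ATP9A, GARIN5B and LRRD1 rest on 1 of 2 probes, and that of ABCC9 on 1 of 3. Their other probes were above background on neither array, so these bounds hold for single probes.

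The gene lists that follow were fixed before the data were examined, and each list's percentile is that of its median among 10000 random lists of its size, matched on mean expression, which describes these arrays only. Members that made up a count of 5 or fewer were also named, chosen after their values were seen.

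**Figure D2:**
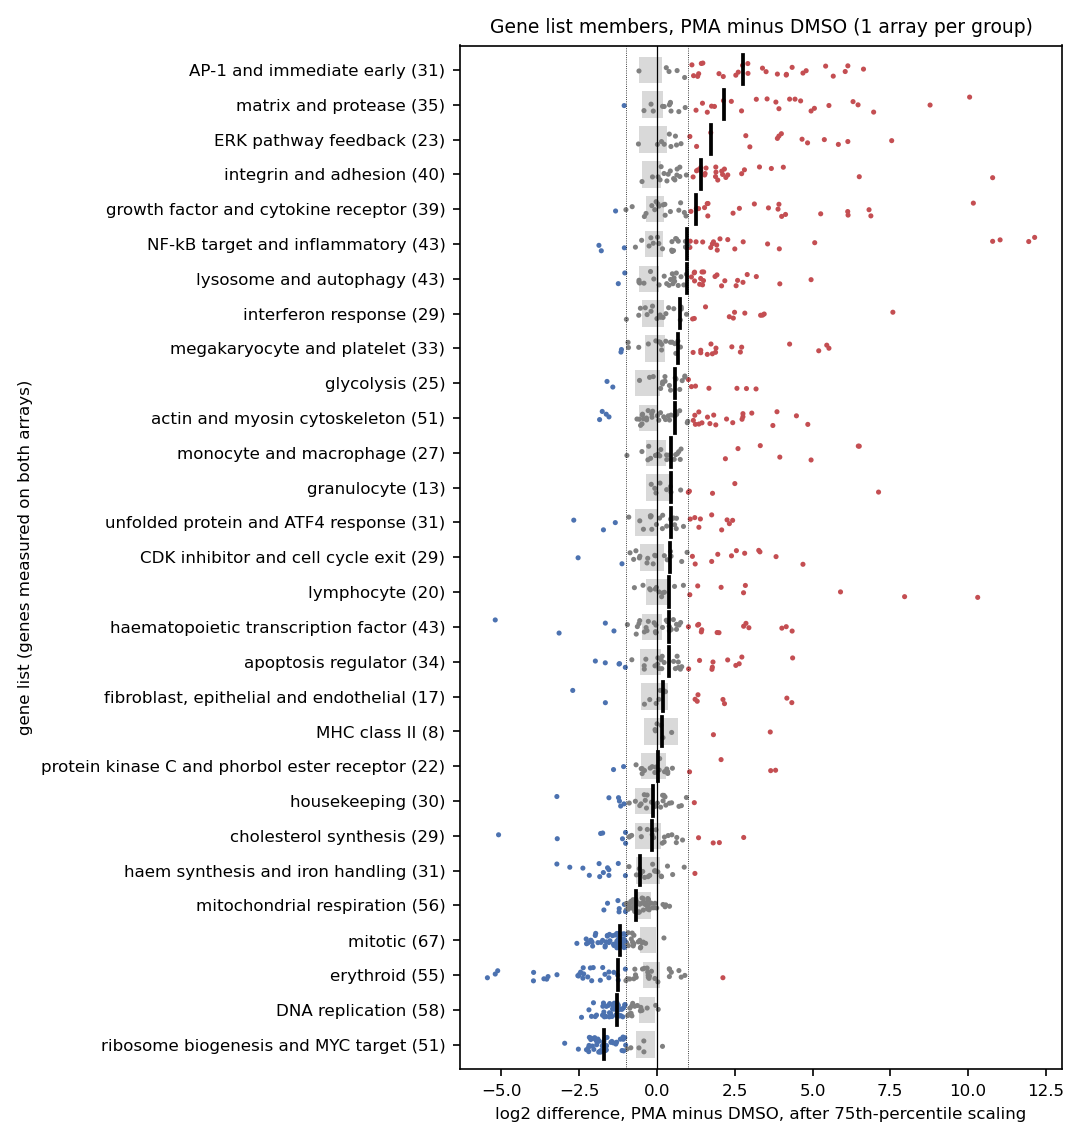
Each point is 1 member of a gene list, placed by its log2 difference, PMA minus DMSO (x axis), with the number of measured members beside each list's name (y axis). Black bars are medians, grey boxes span the central range of the medians of random lists, and dotted lines mark 2-fold. Medians run from -1.70 for ribosome biogenesis genes to 2.75 for immediate early genes.

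Of 55 erythroid genes, 29 were at least 2-fold lower, 25 under 2-fold apart and 1, TRIM10 (2.12), higher, with a median of -1.24 (percentile 0). The lower members included HBZ, KLF1, TRIM58 and PKLR. Both alpha-globin genes, named after their values were seen, were lower, HBA1 by a difference of -2.36 and HBA2 by -2.52. The fetal gamma-globin genes HBG1 (-0.28) and HBG2 (-0.46), near-identical copies, lay under 2-fold apart and turned to 0.46 and 0.27 when the arrays were scaled to the spike-in probes. Their 5 probes were among the brightest on the DMSO array, with signals of 128740 to 265413. Among 31 haem synthesis and iron handling genes, 12 were lower, 18 under 2-fold apart and 1, CPOX (1.22), higher. FECH (-2.17) and BLVRB (-2.38), which encode enzymes of haem synthesis and bilirubin formation, and the iron exporter gene SLC40A1 (-2.80) were among the lowest. The median of this list, -0.53 (percentile 9.59), turned to 0.20 under spike-in scaling. TFRC, the transferrin receptor gene, was at -1.54.

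Of 33 megakaryocyte and platelet genes, 15 were higher, 16 under 2-fold apart and 2, GP1BB (-1.16) and ANGPT1 (-1.14), lower, with a median of 0.67 (percentile 99.99). THBS1 (5.53), a platelet granule protein gene, CD9 (5.46), a tetraspanin of the platelet surface, PTGS1 (5.20), the gene of cyclooxygenase 1, and SPARC (4.26) were the highest. ITGA2B, the platelet integrin alpha subunit gene, was at 1.90. ITGB3, which encodes the partner of ITGA2B, was well above background only on the PMA array with 3 probes (bound 7.22), as were MYLK (7.77), CLU (3.08), MYL9 (2.61) and RAB27B (0.57), while CD36 (bound -0.92) and F13A1 (-0.08) were so only on the DMSO array. Among members chosen after their values were seen, the platelet genes PF4 (0.15) and GP9 (0.49) were under 2-fold apart, while GP6 (1.78), the platelet collagen receptor gene, was higher.

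Among 43 haematopoietic transcription factor genes, 13 were higher, 26 under 2-fold apart and 4 lower, namely KLF1, IKZF1 (-3.15), MYB (-1.66) and TCF3 (-1.38), with a median of 0.39 (percentile 99.92). EGR1 (4.35), an early growth response factor, MAFF (4.16) and BCL6 (4.02) were the highest. GATA1, the factor shared by erythroid and megakaryocytic cells, was at -0.04 and turned positive under quantile scaling (0.11), without scaling (0.13), under the percentile of detected probes (0.10) and under spike-in scaling (0.70). GATA2 was at 0.76 and RUNX1 at 0.63. FLI1, a factor of megakaryocytic genes, was well above background only on the PMA array (bound 1.88), as were EGR2 (5.36) and RUNX3 (0.47).

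Marker lists of other blood cells also had positive medians. Of 27 monocyte and macrophage genes, 7 were higher, none lower and 20 under 2-fold apart, with a median of 0.46 (percentile 99.69). ITGAX (6.50), the CD11c integrin gene, CSF1R (6.47), the receptor gene for macrophage colony-stimulating factor, CTSL (4.95) and CD68 (3.95) were the highest. Of 13 granulocyte genes, 5 were higher, MPO (7.12), the myeloperoxidase gene, CHI3L1, FPR1 (1.79), PRG2 (1.04) and CSF3R (1.01), none lower and 8 under 2-fold apart, with a median of 0.45 (percentile 95.76). Among 20 lymphocyte genes, 8 were higher, none lower and 12 under 2-fold apart, with a median of 0.40 (percentile 98.16). GZMB, CCR7 (7.96), a chemokine receptor gene of lymph node homing, IL7R (5.90) and CD3D (2.84) led that list. Background correction by the normexp model gave medians of 0.22, 0.17 and 0.17, and the stricter signal filter gave 0.73 for monocyte, 0.31 for granulocyte and 0.83 for lymphocyte genes.

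Of 17 fibroblast, epithelial and endothelial genes, 7 were higher, 8 under 2-fold apart and 2, MUC1 (-2.71) and EPCAM (-1.66), lower, with a median of 0.21 (percentile 91.11) that became 0.59 with 7 bounded members at their bound. COL6A3 (4.33) and KRT8 (4.18) were the highest. The 4 probes of KRT18 disagreed, with differences of -0.25 to 3.37 around a mean of 2.17, and KRT8 and KRT18 share sequence with many pseudogenes. Of 8 MHC class II genes, HLA-DPB1 (3.64) and HLA-DPA1 (1.82) were higher, none was lower and 6, among them CIITA (0.47) and HLA-DMA (0.19), were under 2-fold apart, with a median of 0.16 (percentile 62.56). The MHC class II median was 0 under median scaling and -0.06 under the stricter signal filter.

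Genes of cell division were lower as groups. Of 67 mitotic genes, 49 were lower, none higher and 18 under 2-fold apart, with a median of -1.20 (percentile 0). CENPM (-2.57), a centromere protein gene, CDC25A (-2.27), a phosphatase that activates cyclin-dependent kinases, NCAPH (-2.26) and CCNA2 (-2.22), the cyclin A2 gene, were the lowest. Among 58 DNA replication genes, 43 were lower, none higher and 15 under 2-fold apart, with a median of -1.30 (percentile 0). POLE2 (-2.42) and POLD2 (-2.04), subunits of replicative polymerases, GINS1 (-2.19) and ORC1 (-2.10), parts of the helicase and the origin recognition complex, led that list. Ribosome biogenesis and MYC target genes had the lowest median, -1.70 (percentile 0), with 45 of 51 lower, none higher and 6 under 2-fold apart. BOP1 (-2.97), UTP20 (-2.27) and NOP16 (-2.20), which act in ribosome assembly, and SRM (-2.53), the spermidine synthase gene, were the lowest. MYC itself was at -0.58, with probes at -1.53 and 0.38, and turned to 0.16 under spike-in scaling.

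Of 29 CDK inhibitor and cell cycle exit genes, 11 were higher, 16 under 2-fold apart and 2, CCND2 (-2.54) and CDKN2C (-1.12), lower, with a median of 0.43 (percentile 99.74). BTG2 (4.69), an antiproliferative gene, CCNG2 (3.31) and CDKN1A (3.27), which encodes the CDK inhibitor p21, were among the highest, together with CCND1 (3.83), the cyclin D1 gene, which drives rather than ends the cycle. Among 34 apoptosis regulator genes, 10 were higher, 19 under 2-fold apart and 5 lower, CASP6 (-1.98), BIRC5 (-1.66), CYCS (-1.22), BID (-1.20) and CASP2 (-1.02), with a median of 0.38 (percentile 99.93). BMF (4.36) and TNFRSF10B (2.64), which promote cell death, and MCL1 (2.54), which opposes it, were among the highest. The apoptosis median was 0.63 without a background filter.

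Immediate early genes had the highest median of the lists, 2.75 (percentile 100). Of 31 AP-1 and immediate early genes, 26 were higher and 5, MYC, SRF (0.30), FOSL1 (0.39), JUND (0.65) and FOSL2 (0.89), under 2-fold apart. FOSB (6.64) and FOS (6.05), subunits of AP-1, PHLDA1 (6.14) and the nuclear receptor gene NR4A2 (5.67) were the highest, and EGR3 (7.40), ARC (5.90), EGR2 and EGR4 (3.77) had bounds on the PMA array alone. Among 23 ERK pathway feedback genes, 14 were higher, none lower and 9 under 2-fold apart, with a median of 1.73 (percentile 100). DUSP5 (7.55), a phosphatase that inactivates ERK, PHLDA1 (6.14), RGS2 (5.83) and ERRFI1 (5.38), an inhibitor of the EGF receptor, led them, and SPRY1 (2.97), DUSP6 (1.99) and EPHA4 (0.45) were bounded.

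Protein kinase C and phorbol ester receptor genes, the targets of PMA and their relatives, were little apart as a group. Of 22, 16 were under 2-fold apart, 4 were higher and 2 lower, with a median of 0.02 (percentile 72.71) that was negative under median scaling (-0.14), quantile scaling (-0.05), normexp correction (-0.03) and the stricter signal filter (-0.22), and near 0 with the brightest probe of each gene. DGKI (3.81), a diacylglycerol kinase gene, RASGRP2 (3.66), PRKCA (2.06), the protein kinase C alpha gene, and PRKCZ (1.05) were the higher members, and DGKD (-1.40) and PRKCQ (-1.07) the lower ones. RASGRP3 (bound 5.89), PRKCE (4.72) and DGKG (3.35) were well above background only on the PMA array, and PRKD1 only on the DMSO array.

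Among 43 NF-kB target and inflammatory genes, 20 were higher, 20 under 2-fold apart and 3, TRAF2 (-1.86), NFKBIB (-1.79) and SOD2 (-1.05), lower, with a median of 0.98 (percentile 100). Besides CCL2, CCL3, CCL4 and CD44, 6 members had bounds on the PMA array alone, led by IL1B. The median was 0.61 after normexp correction, 0.63 under the stricter filter and 1.52 with no filter. Of 29 interferon response genes, 11 were higher, none lower and 18 under 2-fold apart, with a median of 0.75 (percentile 100). HLA-F (3.45), HLA-E (3.39) and HLA-B (3.33), MHC class I genes, and ISG20 (7.58), an exonuclease gene, were the highest. This median was 0.45 after normexp correction and 0.36 with no filter.

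Adhesion and matrix genes were higher as groups. Of 40 integrin and adhesion genes, 24 were higher, none lower and 16 under 2-fold apart, with a median of 1.41 (percentile 100), led by CD44, ITGAX, TNS1 (4.06), which links integrins to actin, and ITGB5 (3.68). Among 35 matrix and protease genes, 23 were higher, 11 under 2-fold apart and 1, LAMA5 (-1.05), lower, with a median of 2.14 (percentile 100). LOXL2, the interstitial collagenase gene MMP1 (8.78), the tissue plasminogen activator gene PLAT (6.96) and the protease inhibitor gene SERPINB2 (6.46) were the highest. Of 51 actin and myosin cytoskeleton genes, 20 were higher, 27 under 2-fold apart and 4, EVL (-1.84), ANXA1 (-1.76), MYH10 (-1.63) and CNN2 (-1.54), lower, with a median of 0.58 (percentile 100). TPM4 (4.85), a tropomyosin gene, S100A10 (4.48), S100A6 (3.86) and SPTAN1 (3.73), the non-erythroid alpha-spectrin gene, led that list.

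Of 39 growth factor and cytokine receptor genes, 21 were higher, 17 under 2-fold apart and 1, FGFR3 (-1.33), lower, with a median of 1.27 (percentile 100) that was 0.76 after normexp correction. INHBA, PDGFB (6.88), a platelet-derived growth factor gene, IL11 (6.82), a cytokine that acts on megakaryocytes, and IGF1R (6.14) were the highest. Among 43 lysosome and autophagy genes, 21 were higher, 20 under 2-fold apart and 2, LAMP1 (-1.24) and ATP6V1A (-1.03), lower, with a median of 0.95 (percentile 100). CTSL and CTSB (3.19), which encode cathepsins, CD68 and WIPI1 (2.90) led them.

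Of 25 glycolysis genes, 7 were higher, 16 under 2-fold apart and 2, LDHB (-1.60) and PFKM (-1.42), lower, with a median of 0.59 (percentile 99.99), led by the lactate exporter gene SLC16A3 (3.18), the glucose transporter gene SLC2A3 (2.88), ENO2 (2.57) and HK3 (1.67). Among 56 mitochondrial respiration genes, 7 were lower, none higher and 49 under 2-fold apart, and the median of -0.66 (percentile 3.02) turned to 0.08 under spike-in scaling. ATP5MC1 (-1.71), a subunit of ATP synthase, CYC1 (-1.59), NDUFA9 (-1.25) and CYCS (-1.22) were the lowest. Cholesterol synthesis genes went both ways, with 7 of 29 lower, 4 higher and 18 under 2-fold apart. The lanosterol synthase gene LSS (-3.20) was among the lowest, and STARD4 (2.79), MSMO1 (2.01), SQLE (1.81) and TM7SF2 (1.34) were the higher ones. The cholesterol median, -0.15 (percentile 75.99), was 0.01 under quantile scaling, 0.01 without scaling and 0.58 under spike-in scaling. Of 31 unfolded protein and ATF4 response genes, 9 were higher, 19 under 2-fold apart and 3, the cystine transporter gene SLC7A11 (-2.67), PSAT1 (-1.72) and ATF5 (-1.34), lower, with a median of 0.44 (percentile 100), and DDIT4 (2.43), DNAJB9 (2.33) and PPP1R15A (2.25) were the highest.

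Of 30 housekeeping genes, 23 were under 2-fold apart, 6 lower and 1, B2M (1.20), higher, and TFRC, TUBB (-1.24) and SNRPD3 (-1.21) were among the lowest. Their median, -0.12 (percentile 94.94), was 0.04 under quantile scaling, 0.05 without scaling, 0.03 under the percentile of detected probes and 0.62 under spike-in scaling. The 7 spike-in probes well above background on both arrays lay between -0.82 and -0.54, with a median of -0.73.

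The median of all 14470 genes, -0.11, moved by -0.16 under median scaling, 0.17 without scaling, 0.14 under the percentile of detected probes and 0.73 under spike-in scaling. Genes higher on the PMA array made up 46.2% of those at least 2-fold apart, against 57.2% without scaling and 88.7% under spike-in scaling. The share was lower under median scaling (36.7%) and under the stricter signal filter (39.6%). The erythroid, mitotic, replication and ribosome biogenesis medians stayed negative under every scaling, at -0.51, -0.47, -0.57 and -0.97 with the spike-in probes, but all 4 were then under 2-fold. With 1 sample per group, PMA treatment could not be told apart from any other difference between the 2 samples.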

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

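Probe targets with no approved gene symbol lay outside the comparison of named genes. Differences of at least 2-fold appeared there too, in no larger share among those measured on both arrays. Of 6202 such targets measured on both arrays, 569 (9.2%) were at least 2-fold higher and 937 (15.1%) at least 2-fold lower on the PMA array. Among named genes the shares were 13.7% and 15.9%. The largest difference was 7.57, against 12.14 among named genes. Another 241 were at least 2-fold higher on the PMA array by their bound, among 402 seen on that array only, and 204 were at least 2-fold lower by their bound, among 957 seen on the DMSO array only. For named genes these were 511 among 770 and 157 among 826, the latter a slightly smaller share. No explanation was tested for these targets, since their transcripts could not be named with the gene table used.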

How the results depend on the processing

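No paired analysis was possible because each group had 1 array, which also ruled out leaving out a replicate, and no slide block applied since both arrays lay on 1 slide. No named gene at least 2-fold apart, and no list outside the central range of random lists, changed sign. Only these could count as reversed. Within that range, the haem, protein kinase C, cholesterol, MHC class II, mitochondrial and housekeeping medians changed sign under some alternatives. Of 319 list medians under the alternatives, 86 moved by at least the SD of the medians of their matched random lists. Of these, 29 did so under the spike-in scaling that was chosen after seeing the data. Of 1375 values of named genes, 255 moved, 142 of them under that scaling. Of 26 counts, 8 moved by over 1.5 times. Without that scaling, 113 of 1233 gene values moved, 76 with normexp, 26 with no filter, 8 with the brightest probe and 3 with the strict filter. A gene value counted as moved at a shift of at least 0.51, the pooled SD between probes of one gene. Median scaling, no scaling and the percentile of detected probes shift every gene equally by less, so no gene could move. Lists also shift equally there, so whether a list moved depended on the SD of its random medians. The spike-in shift of 0.73 had to move all 142 genes and all 29 lists, so these rates say little about robustness to scaling. Leaving out saturated probes changed nothing, since no spot was saturated. Signal over background limits dim genes most, and for genes seen on 1 array only a bound can be given. Beyond what each scaling does by its construction, the cause was not tested.

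With normexp correction, which damps differences of dim probes, medians were -1.09 for erythroid, 0.22 for monocyte, 0.17 for granulocyte, 0.17 for lymphocyte, 2.45 for AP-1, 1.30 for ERK feedback, 0.61 for NF-kB, 1.22 for integrin, 1.58 for matrix, 0.45 for interferon and 0.76 for growth factor genes. Of 1398 genes at least 2-fold higher with normexp, 1392 were also so in the main setting, and of 1674 lower 1669.

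With median scaling, medians were -1.40 for erythroid, 0.23 for transcription factor, -1.36 for mitotic, -1.46 for replication, -1.86 for ribosome biogenesis, 0.82 for NF-kB, 1.25 for integrin, 0.42 for actin, 1.11 for growth factor and -0.81 for mitochondrial genes. Quantile normalization gave -0.43 for mitochondrial and 1.17 for lysosome genes. Without scaling, medians were 0.84 for megakaryocyte, -1.08 for erythroid, 0.56 for transcription factor, 0.63 for monocyte, -1.03 for mitotic, -1.13 for replication, -1.54 for ribosome biogenesis, 1.15 for NF-kB, 1.57 for integrin, 0.74 for actin, 1.43 for growth factor, -0.49 for mitochondrial and 0.05 for housekeeping genes. The 75th percentile over detected probes gave -1.10 for erythroid, -1.06 for mitotic, -1.16 for replication and -0.51 for mitochondrial genes.

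With no filter on background, 2995 genes were at least 2-fold higher, and medians were 1.52 for NF-kB, 1.87 for matrix, 0.63 for apoptosis, 0.36 for interferon and 0.88 for growth factor genes. The strict filter gave 0.87 for megakaryocyte, 0.73 for monocyte, 0.83 for lymphocyte, 1.27 for ERK feedback, -0.22 for protein kinase C, 0.63 for NF-kB, 0.43 for actin, 1.54 for matrix and 1.09 for growth factor genes. The brightest probe per gene gave 3.03 for AP-1 genes. With bounded members at their bound, medians were 0.59 for fibroblast, epithelial and endothelial genes and 0.54 for interferon genes. At 1.5-fold, 3056 genes were higher and 4100 lower, at 3-fold 1182 and 824, and over probes 3682 were at least 2-fold lower.

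Spike-in scaling, which adds 0.73 to every difference, gave 4632 genes higher and 592 lower. Medians were then 1.41 for megakaryocyte, -0.51 for erythroid, 0.20 for haem, 1.13 for transcription factor, 1.19 for monocyte, 1.19 for granulocyte, 1.14 for lymphocyte, 0.95 for fibroblast, epithelial and endothelial, -0.47 for mitotic, -0.57 for replication, 1.17 for CDK inhibitor, -0.97 for ribosome biogenesis, 3.49 for AP-1, 2.46 for ERK feedback, 0.75 for protein kinase C, 1.71 for NF-kB, 2.14 for integrin, 1.31 for actin, 2.87 for matrix, 1.12 for apoptosis, 0.58 for cholesterol, 1.49 for interferon, 0.90 for MHC class II, 1.17 for unfolded protein, 2.0 for growth factor, 0.08 for mitochondrial, 1.32 for glycolysis, 1.68 for lysosome and 0.62 for housekeeping genes.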

Other observations

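All tests in this part were chosen only after the result was seen. Among 244 families of gene symbols, metallothionein genes stood out on the PMA array: of 12 measured MT genes, 9 were at least 2-fold higher and none lower, with a median of 4.97. MT1L (6.27), MT2A (6.22) and MT1E (6.18), which encode or resemble metal-binding proteins, were among the highest, although near-identical sequences make single members uncertain. Of 8 measured genes of G protein gamma subunits, GNG8 (6.65), GNG11 (4.72) and 3 others were higher, with a median of 1.73. Collagen genes had a median of 0.63, with 9 of 22 higher, led by COL6A3 (4.33), COL7A1 (4.24) and COL15A1 (4.06).

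Of the 244 families, 22 had medians in the high tail and 32 in the low tail of random lists, the low ones including families of replication, ribosomal RNA processing, nuclear pores and mitochondrial translation. Of 11 MCM genes 8 were lower (median -1.41), of 9 RRP genes 7 (-1.60), of 10 EXOSC genes of the RNA exosome 8 (-1.30), of 22 NUP genes 15 (-1.09) and of 52 MRPL genes of the mitochondrial ribosome 26 (-1.0), and none of these families held a member at least 2-fold higher. Their medians stayed negative under all 6 scalings, at -0.67, -0.86, -0.57, -0.36 and -0.27 with the spike-in probes. Others were outside these themes, such as HAUS genes of the spindle (7 of 8 lower) and ZNF zinc finger genes (50 of 386 lower, 18 higher). The ZNF median was only -0.22 and turned to 0.51 under spike-in scaling. The lower share of ZNF genes was below the 15.9% of all named genes, and few of them were higher.

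Several chemokine and cytokine genes were far higher on the PMA array, a pattern that RNA of other blood cells could also bring. Among 12 measured CCL symbols 5 were at least 2-fold higher, CCL2, CCL3, CCL4 and the copies CCL3L3 and CCL4L1, none was lower, and the family's median was 0.24. For RNA of monocytes or macrophages, 12 abundant genes of these cells with a value had a median of 0.42 (SD 1.99). CSF1R (6.47) and AIF1 (3.32) were higher, while LYZ (-0.97) and CD14 (0.12) were under 2-fold apart. Another 4 listed genes, among them S100A8 and S100A9, were above background on neither array. The needed median of 5 was set with these values known, so it cannot decide this explanation. On the fixed monocyte and macrophage list, 7 of 27 genes were higher, among them ITGAX (6.50), CTSL (4.95) and CD68 (3.95), none was lower and 20 were under 2-fold apart. For RNA of lymphocytes or natural killer cells, 17 abundant genes of these cells with a value had a median of 0.24 (SD 1.81), with the same needed median. CD2 (0.18), LCK (-0.21) and NKG7 (0.06) were little apart, although CD3D (2.84), PRF1 (2.06), CD52 (3.74), IL7R (5.90) and CD79B by its bound (1.69) were higher. These medians took the place of counts of higher genes, 2 of 16 and 5 of 18 on lists that share 14 genes each with the monocyte and lymphocyte lists, of which the first lay exactly on its bound and the second had decided nothing. For cytotoxic lymphocytes as the source of the GZMB signal, 10 other genes of these cells had a median of 0.06 (SD 0.89). The needed median of 5 was again set with the values known, and several of the genes were also on the lymphoid list. PRF1 (2.06) was the highest of them, against 10.31 for GZMB, and 4 of the 14 listed genes were above background on neither array. Most of these marker genes were thus not far higher together with the chemokine genes, but no explanation was excluded. PMA treatment of K562 stays open as an explanation, untested apart from other differences between the 2 samples.

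The gamma-globin genes HBG1 (-0.28) and HBG2 (-0.46) were little apart between the arrays, while HBZ (-5.45) and HBA1 (-2.36) were lower on the PMA array. Compression of bright signals is a candidate explanation, because the gamma-globin probes were among the brightest. Of 42 named probes of other genes at least as bright on the DMSO array, 9.5% were at least 2-fold lower, namely single probes of NPM1, HMGN2P46 and RPLP2 (-1.21 each) and of HMGN2 (-1.13). The spike-in probe in that range, with a signal of 154203, was at -0.54 against -0.82 to -0.59 for 6 dimmer ones. None of the 5 probes at least as bright as the median gamma-globin probe was at least 2-fold lower. Compression therefore stays open, and it cannot be told apart from an unequal difference of the globin transcripts.

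Of 51 keratin symbols measured, 33 were at least 2-fold higher on the PMA array, and none lower. The 25 symbols of KRT8, KRT18 and their pseudogenes had a median of 3.64. The other 26 keratin symbols had one of 0.22, with 8 higher, a larger share than the 13.7% of all named genes. The family's shift thus lay mostly in the symbols of KRT8, KRT18 and their pseudogenes. Shared sequence may count few transcripts many times there, but these medians cannot tell that apart from higher pseudogene transcripts. Whether the transcripts of KRT8 and KRT18 themselves were higher because of PMA was not tested apart from the array.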
